A study of Mus musculus with 4 samples.

How the data were processed

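H3K27ac ChIP-seq was made on mouse Th17 cells grown from naive CD4+ T cells, with 2 IP libraries and 2 input DNA libraries, paired by biological replicate in the labels. Libraries came from 2 independent biological replicates, per the series' design text. The growth protocol gives TGF-β as a range and the treatment label as 0.1 ng/mL. Reads were aligned to GRCm38 (mm10), and Bowtie2 2.3.4.1, SAMtools 1.9, MACS2 2.2.6 and deepTools (no version) are named, per the submitters' processing notes. The input of each replicate served the MACS peak call, per the series' design text. The peak threshold, the settings, any filter, and whether replicates were pooled or peak sets joined are not given in the sources used here.

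The deposited list gives, for each peak, the chromosome, start, end and a name with a running number, and the authors put no score, fold, p-value or signal in it. Its names carry 1 common prefix and no replicate. Starts were taken as counted from 0, because the smallest difference between end and start was exactly 100 bp in 788 peaks, and positions are given counted from 1. Of 56285 peaks, 56284 lay on chromosomes 1 to 19 and X and entered the tests. No peaks overlapped, and 21362 (38.0%) lay at most 1000 bp from the next. Read depth is unknown, so intervals on shares cover the number of genes only and say nothing of sequencing error.

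Genes came from a RefSeq table of GRCm38.p6, the build the submitters name. It gives gene starts and ends without strand, exons or sequence, and 21631 protein-coding genes on chromosomes 1 to 19 and X were used. The plan assumed transcription starts, fold enrichment and q values per peak. In their place, a promoter became the 1000 bp on each side of either annotated gene end, exon and intron became gene body, and domains were ranked by covered length. An annotated outer end can miss an internal start, and a peak at the finish of a gene counts like one at its start. Random placements used the span from the first to the last annotated gene of a chromosome. Assembly gaps in it were not excluded, since no gap table was used here. Peaks were classed in the order gene end, gene body, other annotated gene, intergenic, with an overlap of at least 1 bp.

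The 20 gene lists (404 genes, all matched by symbol) were fixed before the data were examined: the Th17 program, other helper T cell programs, T cell identity, activation, cytokine and TGF-β signalling, metabolism, cell cycle, ribosomal proteins, markers of other cells the culture could hold, and tissue genes. Some genes are on more than 1 list. Gene-end peaks were tested with two-sided Fisher's exact tests against all other protein-coding genes, and acetylated length with 10000 random lists of the same size drawn from the 50 genes nearest in length to each member. Domains were peaks stitched across gaps of up to 12500 bp, above the point where the scaled ranked curve has a slope of 1. Width medians were compared with 100000 permutations. Benjamini-Hochberg adjustment ran over the lists or classes of each test, with a threshold of 0.05. Exact 95% intervals are Clopper-Pearson. On simulated lists of 22 genes among the 21631, the gene-end test called 40 of 40 planted lists and the length test 38 of 40, and each called 0 of 40 lists drawn at random. Planted lists had a peak added at an end of about 60% of their genes, over peaks placed at random. Gene-end peaks are much more common in the real list, and its gene lists hold neighbouring genes. These rates therefore check the code and do not give the power or the false calls in the real list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

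Values are given for named Th17 genes, for regulators and cytokines of other lineages, for up to 3 members per other list with the longest acetylated length and up to 3 in alphabetical order without a gene-end peak, for the 10 longest domains and for the 5 widest peaks, a rule set before the data were examined. Its part on the peaks of highest fold enrichment could not be applied. Some genes that the rule names are not reported here. Cd5 and Socs1 are named because a named domain overlaps them. Examples in the report that stand for a group follow this rule, and other names are said to have been chosen after their values were seen.

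Alternatives set beforehand were other gene-end windows (500 and 2500 bp), the peak midpoint, flanks of 5000 and 50000 bp, merging of peaks at most 1000 bp apart, stitching at 5000 bp, and domains without gene-end peaks. Added after seeing the data were peaks of at least 500 and 1000 bp, placements that move the peaks of a chromosome together, merging or classing by midpoint before widths were compared, a background without olfactory (Olfr) and vomeronasal (Vmn) receptor genes, and any overlap with the gene. Overlap of replicates, q value thresholds, fold enrichment and motif searches were not run, since the list holds no such values and no genome sequence was used here.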

Results

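H3K27ac, an acetylated lysine of histone H3 found at active promoters and enhancers, was profiled by ChIP-seq in mouse Th17 cells, the helper T cells that secrete IL-17. Naive CD4+ T cells of C57BL/6 mice were treated for 72 h with anti-CD3ε at 0.25 µg/mL, anti-CD28 at 1 µg/mL, TGF-β at 0.1 ng/mL and IL-6 at 20 ng/mL, per the treatment labels. The labels name 2 H3K27ac libraries and 2 input DNA libraries, an IP and an input for each of 2 biological replicates. The deposited list for these cells holds 56285 peaks with a position each and no score, fold enrichment or value per library. No value reported here therefore has a replicate error, and the depth of the libraries is unknown. The design holds 1 cell state, so the comparisons were made within the list: where the peaks lay, and which genes they marked. Tests over genes or peaks describe this 1 list, since genes and peaks are not replicates.

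The peaks gathered at genes. Of the peaks on chromosomes 1 to 19 and X, 12840 (22.8%) lay within 1000 bp of an annotated end of a protein-coding gene, against 4.70% ± 0.0897 (SD over 1000 random placements), a ratio of 4.86. A further 26016 peaks (46.2%) lay elsewhere within protein-coding genes, against 37.9% ± 0.203. Most of this excess was lost with peaks of at least 500 bp only, a setting chosen after the data were seen (38.7% against 37.4%). Intergenic peaks numbered 12934 (23.0%), against 48.7% ± 0.209, and 4494 (7.98%) touched other annotated genes, against 8.70% ± 0.122. The excess at gene ends had a one-sided permutation p of 0.001, and all 4 classes differed from the placements at an adjusted two-sided permutation p of 0.002, in each case the smallest that 1000 placements can give. These placements moved each peak separately. With the peaks of a chromosome moved together, chosen after the data were seen, the SDs were larger. They were 0.196 at gene ends, 0.811 in gene bodies, 0.323 at other annotated genes and 0.860 between genes. All 4 classes still passed, other annotated genes with the highest adjusted permutation p, 0.026. The gene table used has no strand, so a gene end here is either end, start or finish. Of 13890 genes at least 10000 bp long, 951 had peaks at both ends, 7592 at 1 end and 5347 at neither.

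Peaks at gene ends were the wider ones. Their median width was 1482 bp (quartiles 704.75 and 2319.25 bp), against 453 bp (224 and 1063 bp) elsewhere, a difference of 1029 bp (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). A wide peak is more likely to touch a window by chance. With peaks classed by their midpoint, chosen after the data were seen, the medians were 1393 and 475 bp, a difference of 918 bp (permutation test with 10000 resamples, p = 0.0001, the smallest they can give). By overlap, gene-end peaks made up 37.7% of the acetylated length. Over all peaks the median was 579 bp and the range 100 to 74290 bp, and together the peaks covered 64.6 Mb, or 2.47% of the annotated span. The 25669 peaks under 500 bp were 45.6% of the list and 10.2% of its covered length. Merging peaks at most 1000 bp apart left 34923, and 30616 were at least 500 bp wide.

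Genes of the Th17 program were broadly acetylated. Of 30 genes fixed as the program before the data were examined, 26 (86.7%, exact 95% interval 69.3 to 96.2%) had a peak at a gene end, against 53.8% of the other protein-coding genes (Fisher's exact test, adjusted p = 0.00036 over 20 lists). The acetylated length within the gene and 20000 bp on each side had a median of 18400 bp over the program, against 2749 bp (central 95% range 999 to 4933 bp) in random lists matched on gene length (two-sided permutation, adjusted p = 0.00067, where 10000 random lists can give no smaller raw p than 0.0002). The 4 members with no gene-end peak were Rora, Il22, Il1rn and Sgk1.

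The cytokine genes Il17a and Il17f lay in 1 cluster of 36 peaks on chromosome 1 (20693030 to 20803380, GRCm38) that covered 54617 bp. Il17a (20730905 to 20734496), which encodes IL-17A, had 14 peaks and 24761 acetylated bp in and around it, and Il17f (20777146 to 20785274) had 15 peaks and 23444 bp. Rora, which encodes the nuclear receptor RORα, had 102 peaks and 155730 acetylated bp in and around it, 154330 bp of this inside the gene of 734843 bp (chromosome 9, 68653404 to 69388246), yet no peak within 1000 bp of its annotated ends. Il21, which encodes the cytokine IL-21, had 33621 bp (chromosome 3, 37222759 to 37232636). Among receptors, Il23r had 25062 bp, Il1r1 20666 bp and the chemokine receptor Ccr6 17400 bp, 12508 bp of it in 1 peak. Among genes of like length, Il23r and Ccr6 lay at percentile 98.3 and Il1r1 at 89.3.

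Among transcription factor genes of the program, a peak of 21392 bp (chromosome 13, 30747053 to 30768444) spanned all of Irf4, which had 30165 bp in all. Stat3, the transducer of IL-6 signals, had 31275 bp in 27 peaks and Batf 28523 bp in 20. Each of these 3 genes, Il17a, Il17f, Rora and Il21 lay at percentile 98.3 or higher among genes of like length. Maf had 7601 bp (percentile 84.3) and Ahr, which encodes the aryl hydrocarbon receptor, 9461 bp (percentile 87.8). Il22, a cytokine gene that Ahr is known to control, had no peak nearer than 9181 bp and 767 acetylated bp in its flanks, at the 40.5th percentile.

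**Figure D1:**
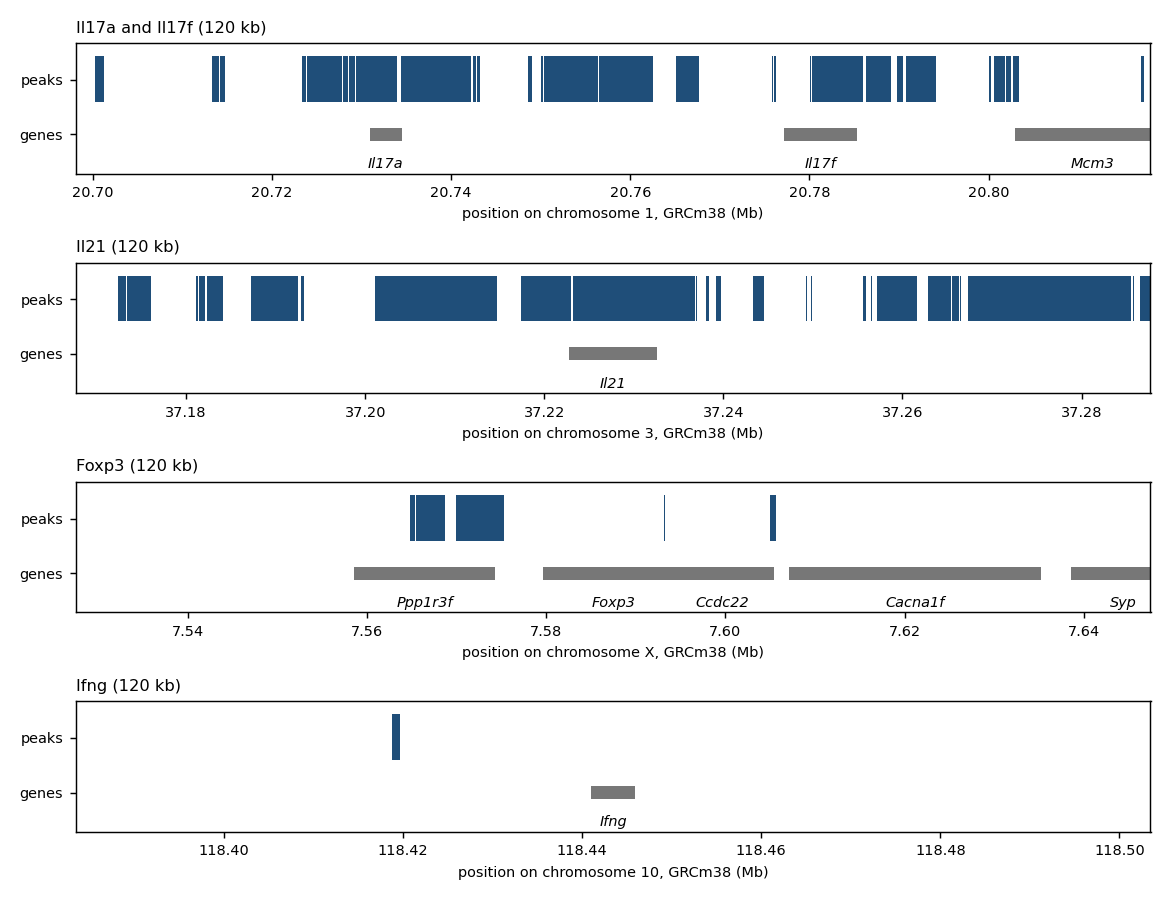
Maps of 120 kb around Il17a and Il17f, Il21, Foxp3 and Ifng on GRCm38; the x axis is the position in Mb, dark blocks are H3K27ac peaks and grey blocks protein-coding genes. The windows hold 32, 26, 5 and 1 peaks in that order, and the only peak in the Ifng window lies 21402 bp from the gene.

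Genes of other helper T cell programs were marked to different extents. Ifng, the signature cytokine gene of Th1 cells, had no peak within 20000 bp (chromosome 10, 118441046 to 118445894), and Eomes had 1774 acetylated bp at the 38.1st percentile of genes of like length. Tbx21, which encodes the Th1 regulator T-bet, had 13204 bp in 8 peaks (percentile 94.8), with its widest peak outside the gene. Of the Th1 and cytotoxic list, 14 of 21 genes had a gene-end peak (66.7%, exact test, adjusted p = 0.28) and the median acetylated length was 3784 bp against 2323 bp in matched lists (permutation, adjusted p = 0.18), so neither test was passed. Its longest acetylated members were Il12rb2 (39344 bp), which borders Il23r, and Runx3 (24618 bp), while Ccl5, Cd8a and Gzma had no gene-end peak.

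The Th2, Treg and Tfh lists had longer acetylated stretches than matched genes. The Th2 list had a median of 9424.5 bp (permutation, adjusted p = 0.0032), led by Il4ra (45847 bp), Ccr4 (24253 bp) and Nfil3 (21412 bp). Gata3, the Th2 regulator, had 11802 bp, 10850 bp of it inside the gene. Il4 had 6356 bp, of which only 412 bp lay inside the gene and the rest in its flanks. Il5 and Ptgdr2 had no gene-end peak. The Treg list had a median of 9908 bp (permutation, adjusted p = 0.00067), led by the activation receptors Il2ra (49704 bp), Ctla4 (28613 bp) and Tnfrsf18 (27462 bp). Foxp3 itself, the Treg regulator, had no gene-end peak and 105 bp of peak inside the gene; most of the 9908 bp in its window lay over or beside neighbouring genes. Foxp3 is the middle of the 17 Treg genes by acetylated length, so the list's median is this same value. Klrg1 and Itgae also lacked a gene-end peak. The Tfh list had a median of 15492 bp (permutation, adjusted p = 0.0011), led by Il6ra (47164 bp), Tox (40412 bp) and Cd200 (38026 bp), and Bcl6, the Tfh regulator, had 13441 bp. Ascl2 and Cxcl13 had no peak in the window. Il10, a cytokine gene several of these cells can use, had 7193 bp.

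By gene-end peaks these 3 lists also passed, with 12 of 14 Th2 genes (exact test, adjusted p = 0.022), 14 of 17 Treg genes (0.032) and 11 of 13 Tfh genes (0.032). These calls were lost when olfactory and vomeronasal receptor genes were left out of the background (exact test, adjusted p = 0.060 for each), and with peaks of at least 500 bp only (0.19, 0.16 and 0.11). Over the 5 alternatives, these exact tests gave adjusted p of 0.046 to 0.83 for Th2, 0.0032 to 0.25 for Treg and 0.060 to 0.12 for Tfh. In a comparison chosen after the data were seen, the Th17 genes had a median percentile of 97.3 among genes of like length. Members of both lists left out, this was higher than the 63.4 of the Th1 list (permutation test with 100000 resamples, adjusted p = 0.0052), the 84.6 of the Th2 list (0.037) and the 85.3 of the Treg list (0.037). Against the Tfh list the values were 96.5 and 94.3 and did not differ past the threshold (permutation, adjusted p = 0.59). Such contrasts also depend on list make-up, since the Th1 list holds cytotoxic genes such as Gzma as well. Long stretches were not particular to the Th17 program, with its median of 18400 bp. Medians were 18592 bp for activation, 20918 bp for JAK-STAT and 24713 bp for T cell identity genes, and shorter for the remaining lists.

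T cell identity and signalling genes were acetylated at nearly every member. All 25 genes of T cell identity and receptor signalling had a gene-end peak (exact test, adjusted p = 1.5e-06), with a median acetylated length of 24713 bp against 2930 bp in matched lists. Lef1 (76267 bp), a transcription factor of the T lineage, and Ets1 (75654 bp) had the longest stretches. Of 25 activation genes, 24 had a gene-end peak (exact test, adjusted p = 1.7e-05) and the median was 18592 bp, with Nfkb1 (71726 bp), Bcl2l1 (51995 bp) and Il2ra (49704 bp) at the top. Bcl2l1 was the 1 member without a gene-end peak. In JAK-STAT and cytokine signalling 23 of 24 genes had a gene-end peak (exact test, adjusted p = 2.7e-05) and the median was 20918 bp. Its longest were Il6ra and Il4ra, which encode receptor chains for IL-6 and IL-4, and Cish (37479 bp), an inhibitor induced by STAT5; Stat4 lacked a gene-end peak but had 25307 bp. All 20 TGF-β signalling genes had one (exact test, adjusted p = 1.4e-05), with a median of 12671.5 bp, led by Ski (36050 bp), the inhibitory Smad7 (30534 bp) and Furin (29594 bp). The lengths of these 4 lists exceeded those of matched lists at an adjusted permutation p of 0.00067.

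Growth and metabolic genes were marked at their ends. Gene-end peaks were found at 17 of 19 glycolysis genes (exact test, adjusted p = 0.0031), 22 of 23 cholesterol synthesis genes (4.5e-05), 26 of 26 cell cycle genes (1.1e-06) and 30 of 30 ribosomal protein genes (2.3e-07). Median acetylated lengths were 8721 bp in glycolysis (permutation, adjusted p = 0.002), 5611 bp in cell cycle (0.036) and 6297.5 bp in ribosomal protein genes (0.0027). Cholesterol synthesis had 4652 bp, which did not pass with 20000 bp flanks (permutation, adjusted p = 0.12) and did with 5000 bp flanks (0.0011), the lowest of 3 alternatives that reached up to 0.67. Among glycolysis genes the longest were Pfkp (22336 bp), Hk2 (21617 bp) and the glucose transporter gene Slc2a1 (17249 bp), and Hk1 and Ldha had no gene-end peak although 7870 and 8472 acetylated bp lay in their windows. The G1 cyclin and kinase genes Cdk6 (50036 bp), Ccnd3 (47852 bp) and Ccnd2 (18013 bp) led the cell cycle list. Srebf2, the master regulator of sterol synthesis, led the cholesterol list with 19415 bp, followed by Tm7sf2 (15509 bp) and Fdft1 (8989 bp), the 1 member without a gene-end peak. Rps19 (14881 bp) and Rpl3 (13740 bp) led the ribosomal list.

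Genes of other cell types and tissues were mostly without gene-end peaks. Gene-end peaks were found at 0 of 22 muscle genes (exact test, adjusted p = 4.1e-07), 1 of 22 liver genes (4.4e-06), 2 of 14 erythroid and megakaryocyte genes (0.0078), 4 of 24 myeloid genes (0.00051), 4 of 17 B cell genes (0.020) and 7 of 23 neuron genes (0.038), all lower shares than in the other genes. NK and innate lymphoid markers had 5 of 13, which did not pass (exact test, adjusted p = 0.28). Albumin (Alb), C1qa, Adgre1, Blk, Gata1 and the actin gene Acta1 were among the genes with no gene-end peak. The lower calls of B cell, erythroid and neuron genes were lost with a window of 2500 bp (exact test, adjusted p = 0.25, 0.068 and 0.11), and over the 5 alternatives ranged from 0.0082 to 0.25, 0.0026 to 0.068 and 0.0043 to 0.71. By acetylated length liver genes (median 381 bp, permutation, adjusted p = 0.021) and muscle genes (157 bp, 0.019) were lower than matched lists, and both calls were lost with flanks of 5000 bp (0.076 and 0.13) and of 50000 bp (0.066 each), but not with peaks of at least 500 bp (0.021 and 0.049). The liver difference was -2363 bp as reported, -1488 bp with 5000 bp flanks and -2959 bp with 50000 bp flanks. For muscle these were -2343, -1348 and -3182.5 bp, so the differences did not shrink with the wider flanks. The myeloid median was 230.5 bp (permutation, adjusted p = 0.15), the neuron median 887 bp (0.18), the erythroid median 690.5 bp (0.46), the NK median 1774 bp (0.44) and the B cell median 1821 bp (0.58), none past the threshold. A window can hold a neighbour's peaks: Cd79a, a B cell receptor gene, and the ribosomal gene Rps19 lie side by side and had the same 14881 bp. Ebf1 (30942 bp) had the longest acetylated length on the B cell list, Xcr1 (17198 bp) on the myeloid list and Mbp (30749 bp) on the neuron list. Inside the genes lay 24746 bp for Ebf1, 430 bp for Xcr1 and 28096 bp for Mbp.

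**Figure D2:**
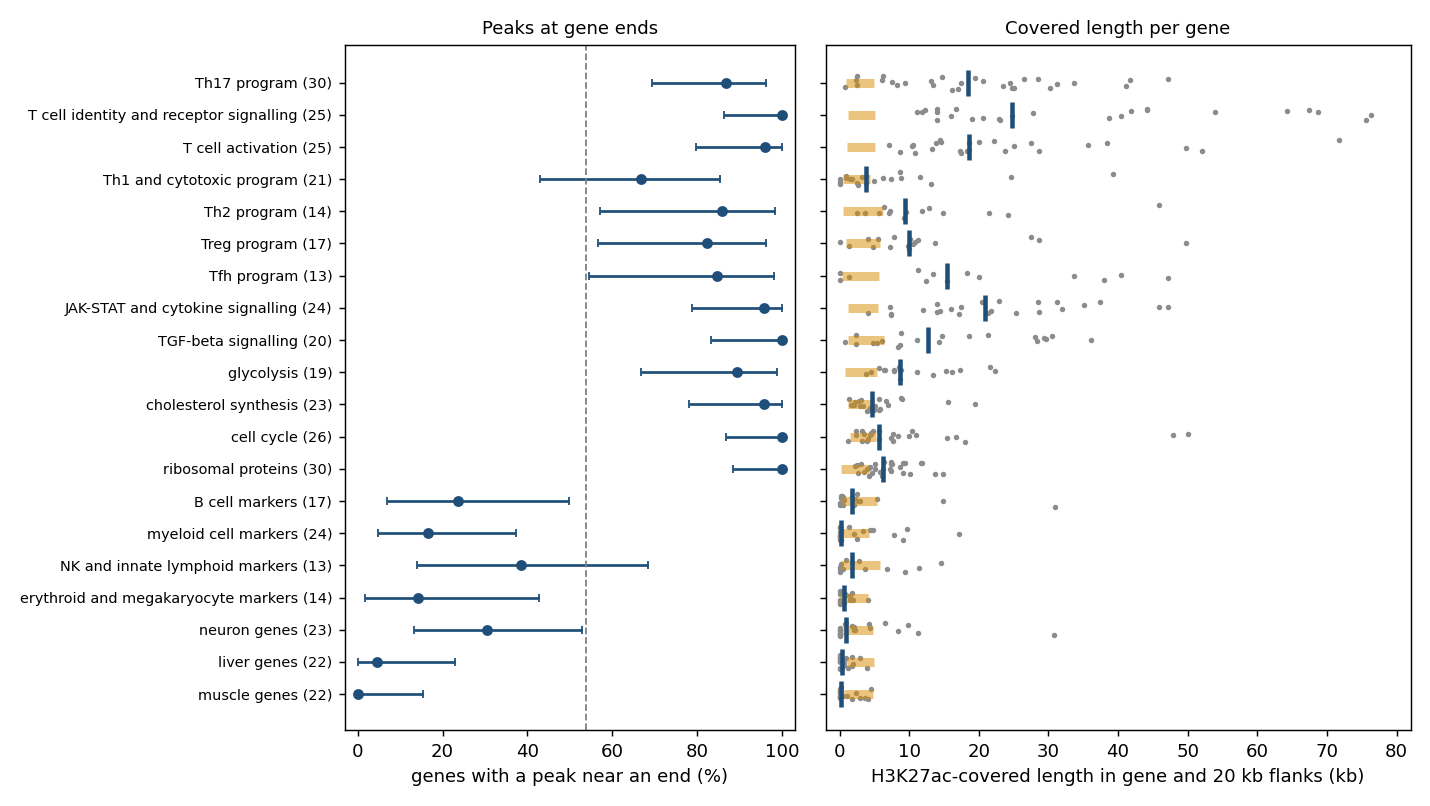
Left, the share of each list's genes (%) with a peak within 1000 bp of a gene end, with its exact 95% interval; the dashed line is the share in all genes, 53.8%, and the number of genes stands in brackets. Right, the acetylated length (kb) within each gene and its flanks, where dots are genes, blue bars list medians and orange bands the central 95% of medians of length-matched random lists; values beyond the axis are not drawn. The medians of the Th17 program (18400 bp) and of T cell identity genes (24713 bp) lie to the right of their bands.

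Long clusters of peaks lay at genes of T cell identity, activation and the Th17 program. Neighbouring peaks were stitched into 18748 clusters, and ranking by covered length with a slope cut-off at 13241 bp set 826 apart as acetylated domains. They held 33.0% of the acetylated length, and their median covered length was 20398.5 bp over a median span of 47194 bp. A gene counted if a domain overlapped it by at least 1 bp. It also counted if it was the nearest, at any distance, to a domain that overlapped no protein-coding gene. Counted in this way were 23 of 25 T cell identity genes (adjusted p = 3.6e-24, Fisher's exact test), 20 of 25 activation genes (9.4e-19), 19 of 24 JAK-STAT genes (7.7e-18) and 20 of 30 Th17 genes (1.9e-16), against about 6.6% of the other genes. The 20 Th17 genes belonged to 21 domains, of which Rora had 3 and Il17a and Il17f shared 1. Further lists past the threshold were Tfh (8 of 13, 1.4e-06), TGF-β signalling (9 of 20, 7e-06), Th2 (7 of 14, 3.6e-05), cell cycle (7 of 26, 0.003), glycolysis (5 of 19, 0.015) and Treg (4 of 17, 0.046). The Treg call was lost under all 3 alternatives (exact test, adjusted p = 0.066 to 0.11), the cell cycle call with stitching at 5000 bp (0.19) and with gene-end peaks left out (0.17), though not with peaks of at least 500 bp (0.0053). The Th2 call was lost with peaks of at least 500 bp (3 of 14, exact test, adjusted p = 0.074). It was kept, with fewer genes, with stitching at 5000 bp (4 of 14, 0.0077) and with gene-end peaks left out (3 of 14, 0.044). The shares were not past the threshold for Th1 (3 of 21, exact test, adjusted p = 0.27), ribosomal (4 of 30, 0.25), neuron (3 of 23, 0.30), B cell (2 of 17, 0.45) and cholesterol genes (2 of 23, 0.74), and 0 genes of the myeloid, NK, erythroid, liver and muscle lists were in a domain. The test was not matched on gene length, and it counts genes that share a domain as independent: the 19 JAK-STAT genes belonged to 16 domains, and the 7 Th2 genes to 5.

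The longest domain covered 185720 bp in 61 peaks over Bach2, a lymphocyte transcriptional repressor (chromosome 4, 32238074 to 32484952). Next came Prkch (139124 bp), which encodes a protein kinase C, and a domain of 110549 bp over the receptor genes Cd28 and Ctla4 (chromosome 1, 60743632 to 60921023). A domain of 105840 bp held the T cell surface genes Cd5 and Cd6, and 1 of 105584 bp on chromosome 3 (37150839 to 37316492) held Il21. The calcium channel gene Itpr1 (104596 bp) and Prkcq (98788 bp), a kinase of T cell receptor signalling, followed. A domain over Clec16a (95242 bp) also took in Socs1, an inhibitor of cytokine signalling. The domain ranked 9 (94276 bp, chromosome 15, 62724033 to 62849607) overlapped no protein-coding gene and had Myc as the nearest, 733671 bp away. Rora had the domain ranked 10 (93824 bp).

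**Figure D3:**
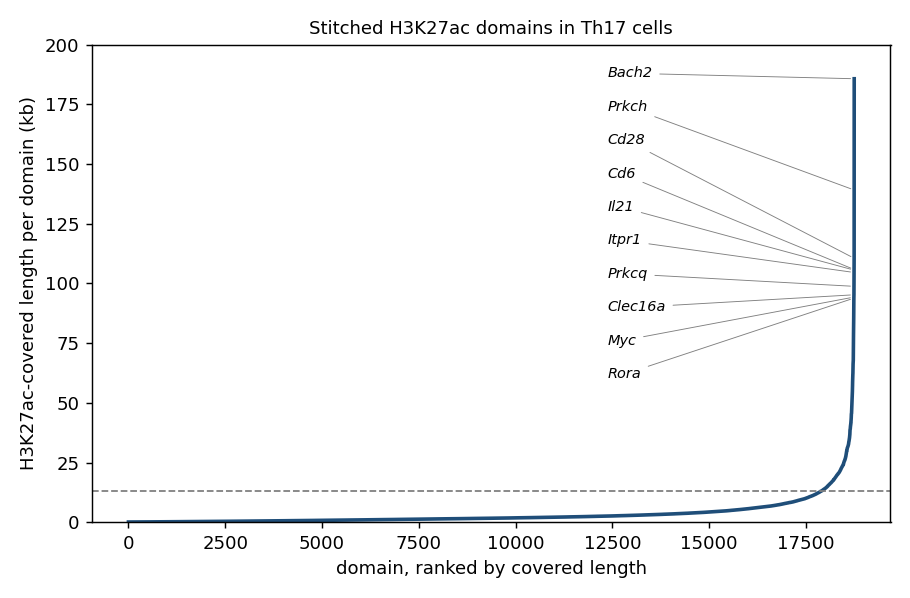
Acetylated length per stitched cluster (kb, y axis) against its rank among 18748 clusters (x axis); the dashed line is the cut-off at 13241 bp and the 10 longest are labelled with the gene they overlap most, or the nearest. The curve bends sharply at its right end, where the cluster at Bach2 reaches 185720 bp.

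The widest single peak, 74290 bp on chromosome 14 (54164994 to 54239283), ran over 46 joining segments and the constant region of the T cell receptor α locus into Dad1. Next in width, peaks of 58472 bp lay in Ets1, 49384 bp in Ptprc, which encodes CD45, 36677 bp in the phosphatase gene Ptpn1 and 35873 bp at Cd28.

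Chromosome X carried fewer peaks per Mb than any autosome. It had 7.33 peaks per Mb of annotated span against an autosome median of 22.3 (range 16.2 to 34.7), a ratio of 0.329. Genes with a gene-end peak were 35.2% on X and 55.2% on the median autosome (range 43.7 to 63.1%). Chromosome Y had 1 peak.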

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

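The comparison of receptor segments and the test on whole sequences were chosen after the values were seen. The tests on runs of missing numbers and on peak width had bounds set before those values were seen, and the comparison with random removal was added after the first run of the numbering test.

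T cell receptor gene segments, which no comparison of the report uses, carried peaks. Of 82 diversity, joining and constant segments of the T cell receptor loci, 66 (80.5%) overlapped a peak, against 0 of 34 of the immunoglobulin loci. The 66 segments met only 6 peaks, and 47 of them lay in the 1 peak of 74290 bp over the α locus, so no p is given for segments. In the β locus 20 of 22 variable, 13 of 13 joining and 2 of 2 constant segments overlapped a peak. In the α and δ loci 48 of 53 joining segments did, and 13 of 119 variable ones. In the γ locus 0 of 7 variable, 0 of 4 joining and 0 of 4 constant segments did. Of 225 immunoglobulin variable segments, 2 overlapped a peak, Ighv8-4 and Ighv1-58, named after their values were seen.

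The running numbers in the peak names reach 71449, and 15164 of them (21.2%) are missing from the list, so the list used here holds fewer peaks than were numbered. Missing numbers between the last peak of a chromosome and the first of the next, together with those below the lowest listed number, were 0.125% of the total. This argues against whole sequences left out as the main cause. Runs of 5 or more held 1.25%, against 0.843% ± 0.170 (SD, highest 1.43%) in 1000 random removals of as many numbers, and this argues against a filter on long stretches of the genome as the main cause. The missing numbers below the lowest listed one, 15, were not counted as a run. Single missing numbers were 60.4% of the total, against 62.1% ± 0.484 (SD) in the random removals. Missing numbers were thus somewhat more grouped than random, and a filter on short stretches stays open. A filter that removed weaker peaks stays open. At least 1 number was missing between 20.8% of neighbouring listed peaks both under 500 bp and 20.7% of those both at least 500 bp. The difference was 0.0570 ± 0.488 (SE) percentage points, but 3.80 points when neighbours at similar distance were compared. A step that kept peaks shared by both replicates could also leave such gaps and could not be tested, and no biological explanation was tested.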

How the results depend on the processing

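The settings on minimum peak width, joint movement of peaks, merged widths, widths by midpoint, background and any overlap were chosen after seeing the data. The excess of peaks at gene ends kept its direction and call under all 5 alternatives (16.3 to 28.3 percentage points over random placement, 18.1 as reported), as did the width difference (750, 861 and 918 bp against 1029 bp), and with peaks placed by midpoint the 3 other classes did too. Of 259 results under an alternative, 216 kept their direction and side of the threshold or, for counts, stayed within 1.5 times the reported one (the X ratio within 1 SD between autosomes), 28 kept their direction and lost the call, and 1 gained it. The Th17 program kept its calls at gene ends in all 5 alternatives (exact test, adjusted p = 0.00013 to 0.0022) and by acetylated length in all 3 (permutation, 0.00044 to 0.00057). Domains numbered 792, 763 and 689 against 826, and the ratio of X to autosomes was 0.337 against 0.329 with peaks of at least 500 bp. The number of peaks was 34923 after merging and 30616 from 500 bp, as those settings merge or remove peaks. Lists with more gene-end peaks than other genes numbered 9 to 11 against 12 as reported, and domain lists 8 against 10. Lists past the threshold with fewer gene-end peaks than other genes numbered 3 with a window of 2500 bp and 6 as reported. Lists past the threshold with shorter acetylated length numbered 0 with flanks of 5000 and 0 with 50000 bp, against 2, and the cause was not tested.

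These differences changed sign, none past the threshold before or after, and the cause was not tested. At gene ends, in percentage points against other genes, the Th1 list had -0.882 with peaks of at least 1000 bp and the NK list 0.705 with any overlap. In domains with stitching at 5000 bp, cholesterol and neuron genes had -0.0857 each, ribosomal -1.10 and B cell genes -4.44. With gene-end peaks left out before stitching, ribosomal genes had -0.741, myeloid 0.0939 and NK 11.3.

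No paired analysis was possible because the list has no value per library, so the replicate numbers were not used, and neither replicate was left out. Thresholds on q, fold enrichment, replicate overlap, motifs and a single start per gene were not run, since the list and gene table hold no such values. Depth is unknown, so a gene without a peak is below this list's unknown threshold, which does not show an absence of acetylation.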

Other observations

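The tests on gene families, microRNA genes, chromosome X and marker genes were all chosen after the data were seen, as were the genes and families named here outside the naming rule.

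Gene-end peaks separated gene families. Among 153 families of at least 15 protein-coding genes with a common symbol stem, 57 had a higher share of genes with a gene-end peak than other genes and 44 a lower one (Fisher's exact tests, Benjamini-Hochberg adjusted). Olfactory receptor genes had 12 of 1110 and vomeronasal receptor genes 2 of 355 (exact test, adjusted p = 2e-114), keratin-associated protein genes (Krtap) 0 of 56 (5.9e-18) and cytochrome P450 genes (Cyp) 15 of 99 (7.2e-14). Zinc finger genes (Zfp) had 303 of 397 (6.5e-19), mitochondrial ribosomal genes (Mrpl) 48 of 49 (6.3e-11), vacuolar sorting genes (Vps) 35 of 35 (4.5e-09) and RNA polymerase subunit genes (Polr) 28 of 28 (3.1e-07). Genes of tandem families share windows and are not independent.

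Of 1228 microRNA genes, 56 lay in acetylated domains, against 21.5 ± 10.2 (SD, highest 92) when domains were placed at random (one-sided permutation, p = 0.025 over 1000 placements). The placements did not keep domains at genes, where the peaks gathered. The test therefore cannot tell an excess at microRNA genes from one at genes in general. Of the 56, 34 overlapped a peak and 22 lay between the peaks of a domain. Mir21a (domain of 50713 bp at Vmp1) and Mir142 (domain of 31700 bp) overlapped a peak, and Mir29a lay between peaks of a domain of 66135 bp. MicroRNA genes lie in clusters, so these counts are not independent.

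Chromosome X had 7.33 peaks per Mb against 22.3 on the median autosome. Lower gene density does not account for this in full, since X had 1.295 peaks per protein-coding gene and the autosomes 1.62 to 3.59. A single copy of X in the cells, or an inactive second copy, may lower detection. The 90th percentile of gene-end peak width was 3216.5 bp on X, between the lowest autosome (3092.4 bp) and the median one (3709.5 bp), so the test leaves this open. No label used here gives the sex of the mice, and no biological explanation was tested.

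Of the B cell and myeloid lists, 8 genes had a gene-end peak: Cd79a, Ebf1, Vpreb1, Cd72, Cd14, Spi1, Xcr1 and Cd68. B cells in the culture are a possible source of the first 4. Of the segments of the 3 immunoglobulin loci, 0 of 34 diversity, joining and constant ones and 2 of 225 variable ones overlapped a peak. These counts give no clear sign of B cells but do not exclude them. The bound was set after the counts were seen, sequence outside the segments was not examined, and a segment without a peak may lie below the list's threshold. Myeloid cells in the culture stay open for the other 4, since 4 of 24 genes of that list had a gene-end peak, neither most of the list nor almost none. A peak of a neighbouring gene inside the window could account for 3 of the 8, Vpreb1 (beside Top3b), Xcr1 (beside Fyco1) and Cd68 (beside Eif4a1 and Mpdu1), since those shared every gene-end peak with the end of another gene. The other 5, including Ebf1 with 30942 acetylated bp, had at least 1 gene-end peak that no other gene end shared.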
